A study of Mus musculus with 2 samples.

How the data were processed

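The series holds single-cell RNA sequencing of mouse molars at E14 and P12, 1 library per stage, from the keratin 14 reporter line that the labels name. Per the labels' protocols, dissociated cells were loaded on a 10x Genomics Chromium controller, libraries were made with a v2 single-cell kit, and sequencing was on a NextSeq500. Per the submitters' processing notes, reads were processed with Cell Ranger 2.0 on mm10. The deposited matrices, made by the authors with Cell Ranger, hold whole UMI counts per gene and cell barcode, without normalization, and their names say that barcodes had been filtered to called cells. The shared protocol text speaks of molars of another postnatal age and, in a later step, of incisors, which differs from the stage labels. The stages used here are those of the sample titles and age fields. The embryonic globin genes Hbb-y, Hba-x and Hbb-bh1 had UMIs in the E14 library and 0 UMIs in the kept P12 cells. That bears on embryonic against postnatal stage and cannot tell P12 from the other postnatal age.

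Each matrix had 48816 features, of which 48709 were mouse gene IDs, 92 were spike-in entries and 15 were transgene entries. Of the mouse IDs, 48349 were in the GENCODE vM21 annotation, which gave the positions of the named genes. The E14 library held 68941114 UMIs in 6916 barcodes (3406 to 68712 per barcode) and the P12 library 12595917 UMIs in 2284 barcodes (2267 to 66071 per barcode). Hemoglobin genes took 19.6% of E14 and 5.38% of P12 UMIs. Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. The gene minimum removed 609 E14 and 153 P12 barcodes, with median hemoglobin shares of 93.3% and 96.8%, and the mitochondrial limit removed 5 and 98. Scrublet, run in scanpy 1.11.5, marked 0% and 0.375% of cells at its own threshold. As planned for marks under 0.5%, the cells with the highest scores were removed instead, at an expected rate of 0.8% per 1000 barcodes, which took 349 E14 and 39 P12 cells.

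Each library was clustered on its own. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen. Genes of the 16 result lists and mitochondrial and ribosomal protein genes were then removed. The steps after that were 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with a fixed seed, which gave 24 clusters at E14 and 21 at P12. A cluster took the class with the highest marker score among 15 classes, given at least 3 markers detected and no excess of another class's markers among its 10 leading genes. A cluster of low depth with none of its class's markers among those genes also stayed unnamed. The score minimum of 0.25 and the level at which a marker counts, 30 CPM, were set after the data were seen. Markers of 9 subtypes do not enter the score, but among the leading genes they count for the class that holds the subtype. Many subtype markers are also members of result lists, such as Amelx, Klk4, Dspp, Bglap, Bmp3 and Tnmd, and the markers of red cells overlap the hemoglobin list. Markers of the 15 classes were left out of the genes named by ratio between classes, but subtype markers were not. P12 cluster 7, mesenchymal by score, kept its name through 2 subtype markers among its leading genes, Bglap2 and Mmp13, against 1 marker of another class. Bglap, Bglap2 and Dspp are reported, so their place in the P12 mesenchyme was partly set by the naming.

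UMIs were summed over the cells of a class and divided by the class total to give CPM. Intervals for CPM are exact Poisson, those for shares exact Clopper-Pearson and those for ratios conditional binomial, all at 95% and for counting error only. In list medians, counts of members and log2 ratios, a sum under 3 UMIs was set to a floor of 3 UMIs over the class sum. A ratio printed as a fold is a bound against that floor for 0 UMIs, and for 1 or 2 UMIs it is the measured ratio with its interval. Where the floor would make the raised side the higher one, the gene was given a ratio of 1. The 4 planned comparisons were epithelium and mesenchyme between stages and epithelium against mesenchyme within each stage. Endothelium between stages was added after the data were seen. With 1 library per stage no test was made, and cells were not treated as replicates.

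The 16 gene lists, the marker lists and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the largest ratio in each direction between stages, or 8 between classes, among genes with at least 200 CPM and a UMI in at least 20% of cells on the higher side. It left out mitochondrial, ribosomal, hemoglobin and sex-linked marker genes, unnamed gene models, class markers in comparisons of classes, and genes over 10 times higher in another class of 20 or more cells of the same library. That last condition marks possible free RNA, and it also marks list members here. To these were added up to 4 members of each list with the largest log2 ratio at 20 CPM or more. Mentions of Dlx5, Sfrp1, Nkd1 and the genes drawn by cluster in later parts were chosen after their values were seen. A list member counted as measured with 3 or more UMIs on either side, and as higher or lower at a 2-fold ratio. Percentiles compare a list's median with 10000 random lists of equal size, each gene drawn from the 100 nearest in mean CPM.

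For mitotic transcripts each cell was thinned to 2000 UMIs and scored for 3 or more UMIs of the mitosis list. Alternatives changed the gene minimum (200, 1000), the mitochondrial limit (5%, 20%), doublet removal, resolution (0.5, 2), list genes in the clustering, joint clustering, TMM scaling, the mean of per-cell CPM, a total without the 20 most abundant genes and other abundant families, the floor (10), the fold limit (1.5, 3) and the thinning and its threshold. Placing unnamed clusters in their best class, and counting lists without members open to free RNA, were added after the data were seen. The procedure was tested on simulated counts with 50 genes at each of 4 known ratios per comparison. Counts were Poisson draws from the class sums, for genes with a mean of at least 20 CPM. They held no variation between cells or libraries, no free RNA and no misnamed cells. The rates that follow therefore cover counting error alone and not genes at lower levels. All of these genes had the right direction, 50 to 68% of those simulated at 2-fold and at least 98% of those at 4-fold or more were called at least 2-fold, and at most 0.214% of unchanged genes were. Reads of near-identical copies, such as Bglap with Bglap2 and Hba-a1 with Hba-a2, cannot be assigned with certainty. Free RNA was not removed from the counts. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.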

Results

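Single-cell RNA sequencing was available for mouse molars at embryonic day 14 (E14) and postnatal day 12 (P12), with 1 library per stage and a keratin 14 driven red fluorescent reporter in both. The series design names epithelial and mesenchymal cells of the molar as its subject, so cells were sorted into classes by marker genes and the classes were compared between stages and with each other. The E14 library held 6916 barcodes and 68941114 unique molecular identifiers (UMIs), and the P12 library held 2284 barcodes and 12595917 UMIs. After filtering, 5953 E14 cells with a median of 8002 UMIs and 2011 P12 cells with a median of 4292 UMIs were kept. With 1 library per stage there was no replicate check and no test, p-value or standard error is given. Levels are the CPM of UMIs summed over a class (UMIs of a gene over all UMIs of the class, scaled as usual), with exact Poisson 95% intervals, and shares of cells carry exact Clopper-Pearson 95% intervals. Both kinds of interval cover counting error only. Ratios are CPM ratios with counting intervals. Where the lower side had 0 UMIs, the ratio is a lower bound computed against a floor of 3 UMIs over the class sum, and with 1 or 2 UMIs the measured ratio is given with its interval. Each list's median log2 ratio is placed as a percentile among 10000 random lists of like expression, as a description of these libraries. A list's mean is given where its sign differs from the median's.

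Mesenchymal cells were the largest class in both libraries. They made up 67.3% of E14 cells (66.1 to 68.5%, 4009 cells in 13 clusters) and 41.3% of P12 cells (39.2 to 43.5%, 831 cells in 5 clusters). Epithelial cells made up 3.85% of E14 cells (3.37 to 4.37%, 229 cells in 1 cluster) and 21.4% of P12 cells (19.6 to 23.2%, 430 cells in 4 clusters). Endothelial cells were 1.39% of cells at E14 (1.11 to 1.73%) and 13.7% at P12 (12.2 to 15.3%). The E14 library also held skeletal muscle cells (4.99%, 4.45 to 5.57%), chondrocytes (4.18%, 3.69 to 4.72%), macrophages (2.52%), glial cells (0.756%) and red cells (8.57%). The P12 library also held perivascular cells (3.73%, 2.94 to 4.65%), macrophages (1.99%), red cells (0.845%) and neutrophils (0.398%). Clusters left unnamed held 6.40% of E14 cells and 16.7% of P12 cells. Each had more markers of another class than of its best-scoring class among its 10 leading genes. The best score was mesenchymal for E14 cluster 14 and P12 cluster 11, endothelial for P12 cluster 14 and osteoclast for P12 cluster 13. Class shares depended on the cell filters and the clustering. Under the alternatives the mesenchymal share was 54.1 to 73.7% at E14 and 40.3 to 48.2% at P12. The P12 epithelial share was 17.2 to 22.8% and the P12 endothelial share 13.5 to 18.5%. The printed intervals do not cover such moves. The chondrocyte share was 0% at Leiden resolution 0.5, with listed genes in the clustering and with both libraries clustered together. The P12 macrophage share was 5.52 to 7.06% under 7 of the alternatives, when cells from unnamed clusters took that name, and the E14 red cell share was 1.13 to 16.5% with other gene minimums. The marker score thresholds behind the naming were set after the data were seen. Muscle and cartilage cells show that the E14 library held tissue other than the tooth germ, and its mesenchymal class was not divided into dental and other mesenchyme. The shares also depend on dissection and dissociation.

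**Figure D1:**
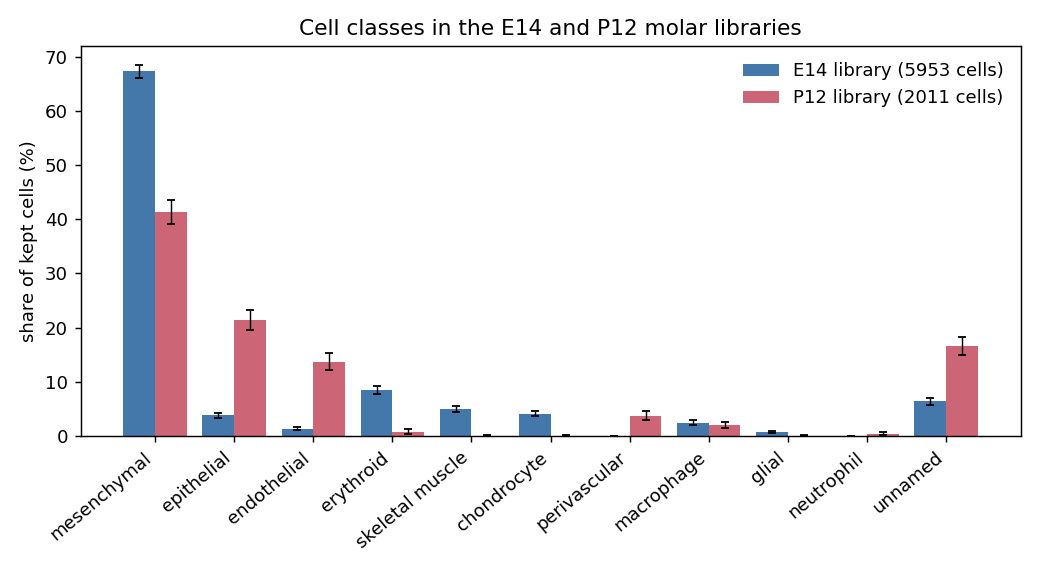
Percent of kept cells (vertical axis, from 0) in each cell class of the E14 and P12 libraries, with exact 95% intervals as error bars. Mesenchymal cells were 67.3% and 41.3%, and epithelial cells 3.85% and 21.4%.

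The comparison of the epithelium between stages asked which genes separate the E14 epithelium, here 1 cluster of 229 cells, from the P12 epithelium, here 4 clusters of 135, 123, 131 and 41 cells. The first of these P12 clusters carried 7 of 9 marker genes of keratinizing oral epithelium. The E14 cluster was not divided into dental and other epithelium either, so both sides can hold epithelium from outside the tooth. All 15 measured enamel matrix and ameloblast genes were at least 2-fold higher at P12, with a median log2 ratio of 6.32 (percentile 100). Amelx encodes amelogenin, the main protein of the enamel matrix (ENSMUSG00000031354.16, mm10 chromosome X, 169176114 to 169187200, protein coding). It stood at 29166 CPM at P12 (28984 to 29348) and had 0 UMIs at E14 (upper limit 1.43 CPM), so it was at least 25113-fold higher. Ambn, which encodes ameloblastin (ENSMUSG00000029288.11, chromosome 5, 88455991 to 88468531, protein coding), stood at 12754 CPM against 0 UMIs, at least 10982-fold higher. Amtn, a gene of maturation-stage ameloblasts, was at 2449 CPM against 0 UMIs, at least 2109-fold higher. Odam, also made by maturation-stage ameloblasts, was at 11075 CPM against 0.774 CPM, a ratio of 14304 (3960 to 118120) that rests on 2 E14 UMIs. Klk4, a protease that clears enamel proteins, was at 810.4 CPM against 0.774 CPM, a ratio of 1047 (289 to 8647) that also rests on 2 E14 UMIs.

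Further genes with the largest P12 to E14 ratios in the epithelium included Calb1, a calcium-binding protein, at 1670 CPM against 0 UMIs (at least 1438-fold higher). The secreted chaperone gene Clu had a ratio of 245 (181 to 342) and the mitochondrial creatine kinase gene Ckmt1 a ratio of 181 (83.0 to 494). Fxyd4, which encodes a regulator of ion transport, had a ratio of 178 (81.4 to 485), and Snap91, for a clathrin assembly protein, 92.7 (44.8 to 231). Csn3, for kappa casein, was at 271 CPM against 0.387 CPM (1 UMI), a ratio of 699 (125 to 27640). Of 12 measured ion and pH transport genes, 9 were at least 2-fold higher and 0 lower (median 2.40, percentile 100). Slc4a4, a bicarbonate cotransporter (ENSMUSG00000060961.14, chromosome 5, 88886818 to 89239653, protein coding), was at 225 CPM against 1.94 CPM, a ratio of 116 (49.6 to 359). The carbonic anhydrase gene Car2 was at 92.0 CPM against 3.87 CPM. Stim1, a calcium sensor, was 13.3-fold higher (8.90 to 20.8). Among 13 basement membrane and adhesion genes, 7 were higher and 3 lower (median 1.73, percentile 100), with Lama3 and Lamb3 at 13.3-fold and 13.2-fold.

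**Figure D2:**
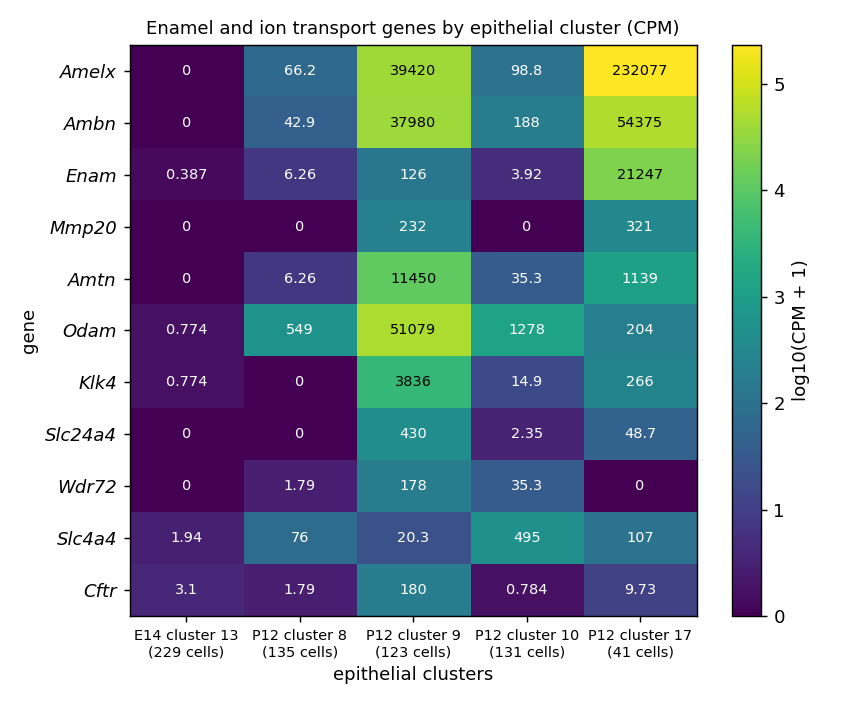
Heat map of the CPM of 11 enamel and ion transport genes in the E14 epithelial cluster and the 4 P12 epithelial clusters, with colour on a log10 scale and the CPM printed in each field. Amelx reached 232077 CPM in P12 cluster 17 and 39420 CPM in cluster 9, while Slc4a4 was highest in cluster 10 at 495 CPM.

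Genes of cell division and fetal growth were lower in the P12 epithelium. All 20 measured mitosis genes were at least 2-fold lower (median -4.64, percentile 0). Ube2c, which drives anaphase, was at 6.49 CPM at P12 and 257 CPM at E14, a log2 ratio of -5.31. The DNA topoisomerase gene Top2a had a log2 ratio of -4.61 and Ccnb1, for cyclin B1, -5.87. Of 18 DNA replication genes, 17 were lower and 0 higher (median -2.70, percentile 0), Rrm2 at -3.67 and Uhrf1 at -4.16. Of 13 fetal growth and imprinted genes, 10 were lower and 0 higher (median -2.54, percentile 0). The RNA-binding protein gene Igf2bp1 (ENSMUSG00000013415.9, chromosome 11, 95957163 to 96005940, protein coding) had 0 UMIs at P12 against 94.8 CPM at E14, at least 107-fold lower. Hmga2, a chromatin protein of growing tissue, was at 6.49 CPM against 151 CPM and Cdkn1c, a growth inhibitor, at 44.8 CPM against 565 CPM. Sox11, a transcription factor of immature cells (ENSMUSG00000063632.6, chromosome 12, 27334264 to 27342574, protein coding), was at 18.9 CPM (14.5 to 24.1) against 599 CPM (569 to 629), and Meis2 at 12.4 CPM against 455 CPM. Cks2, Cks1b, Cenpa, Stmn1, H2afx, H1fx and Tead2 had log2 ratios from -4.07 to -3.23.

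Developmental signalling lists differed in direction in the epithelium. Of 14 FGF pathway genes, 8 were at least 2-fold lower at P12 and 1 higher (median -2.59, percentile 0). The ligand genes Fgf9 and Fgf20 had 0 UMIs at P12 against 28.3 and 34.1 CPM at E14, at least 32.0-fold and 38.5-fold lower. The FGF target genes Etv4 and Etv5 were at 0.590 and 2.06 CPM against 43.4 and 38.3 CPM. Of 24 Wnt pathway genes, 12 were lower and 4 higher (median -0.76, percentile 0.97). The inhibitor genes Kremen2 and Sfrp1 were lower at P12 (log2 ratios -5.74 and -3.41), and Wnt5a was higher, at 102 CPM against 8.52 CPM. Of 21 BMP and TGF-beta pathway genes, 9 were higher and 3 lower (median 0.52, percentile 97.9), with Bmp4 at 54.0 CPM against 1.94 CPM and Tgfb1 at 237 CPM against 15.1 CPM. The 23 odontogenic transcription factors divided into 9 higher and 8 lower (median 0.17, percentile 84.3, mean -0.31). With doublets kept 7 of them were higher and the balance of the counts turned. Without 4 members open to free RNA, 9 were higher and 5 lower of 19. Sox2, a factor of early dental epithelium, was at 7.67 CPM against 111 CPM, and Pax9 and Lef1 had log2 ratios of -3.84 and -4.72. Among 12 hedgehog pathway genes, 1 was lower and 0 higher (median -0.47, percentile 19.5), with Gli3 at -0.99 and Smo at -0.71. That count of 1 depended on the settings and was 0 to 5 under the alternatives, among them 3 with at most 5% mitochondrial UMIs and 4 with doublets kept. Among 6 ectodysplasin pathway genes, 1 was lower, Edaradd at -1.89, and 0 higher (median -0.13, percentile 54.4).

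Of 16 immediate early and stress genes, 15 were higher in the P12 epithelium and 0 lower (median 2.81, percentile 100), with Dusp1 18.3-fold (15.4 to 21.8) and Hspa1a 49.0-fold (24.7 to 114) higher. P12 epithelial cells also had a higher median mitochondrial share (3.01% against 1.56%) and fewer UMIs per cell (median 5315.5 against 9621). Of 10 dentin and bone matrix genes, 5 were higher and 0 lower (median 1.02, percentile 99.7), Alpl at 158 CPM against 6.19 CPM. Of 11 fibrous matrix genes, 4 were higher and 0 lower (median 0.75, percentile 98.5), Col14a1 at 34.5 CPM against 8.52 CPM. In each of these 2 lists 7 measured members were over 10 times higher in another class. That level leaves free RNA possible without showing it as the source, and without these members the higher ones were 2 of 3 and 1 of 4. All 8 hemoglobin and red cell genes were open to free RNA, and 7 were lower at P12 (median -1.79, percentile 0). With Leiden resolution 2, the count of dentin and bone matrix genes at least 2-fold higher was 11 rather than 5. Scaling by the trimmed mean of M values (TMM) moved the median of all genes by 0.20 on the log2 scale.

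The comparison of the mesenchyme between stages set 13 E14 clusters against 5 P12 clusters, of which cluster 7 carried 7 of 7 osteoblast and 5 of 7 odontoblast marker genes. These marker counts used the summed CPM of the cluster, which a few cells can supply. Cluster 7 was mesenchymal by score, but it kept that name only through the osteoblast markers Bglap2 and Mmp13 among its leading genes. Matrix genes were higher at P12. Of 14 dentin and bone matrix genes, 11 were at least 2-fold higher and 1 lower (median 3.83, percentile 100), and of 12 fibrous matrix genes, 10 were higher and 1 lower (median 3.15, percentile 100). Bglap, the osteocalcin gene (ENSMUSG00000074483.2, chromosome 3, 88383501 to 88384464, protein coding), was at 2216 CPM at P12 (2168 to 2265) and 0.358 CPM at E14, a ratio of 6193 (3543 to 11990). Its neighbouring copy Bglap2 was at 720 CPM against 0.179 CPM, a ratio of 4026 (1847 to 10981). Dspp, which encodes the main noncollagenous precursor of dentin (ENSMUSG00000053268.7, chromosome 5, 104170712 to 104180127, protein coding), was at 160 CPM (147 to 174) against 0 UMIs, at least 1790-fold higher. These levels came from few cells. Dspp UMIs lay in 9 of 831 cells and Bglap UMIs in 37, and for each gene 5 cells held 90% of the UMIs. With Leiden resolution 2 the log2 ratio of Bglap was 7.61 rather than 12.60 and that of Bglap2 8.33 rather than 11.98, and with at most 5% mitochondrial UMIs they were 7.65 and 8.63. Under either alternative Dspp had under 3 UMIs in the mesenchyme of both stages and no ratio could be given.

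The genes of broad fibrous matrix were spread over many P12 mesenchymal cells. Lum, for the proteoglycan lumican, had a UMI in 95.4% of cells and was at 3703 CPM against 159 CPM, a ratio of 23.3 (22.6 to 24.1). In P12 epithelial cells, which were deeper (median 5315.5 against 3866 UMIs), 9.07% had a Lum UMI. Aspn, a periodontal ligament proteoglycan (ENSMUSG00000021388.13, chromosome 13, 49544443 to 49567565, protein coding), was at 1467 CPM (1428 to 1507) against 61.0 CPM (58.4 to 63.7), a ratio of 24.0 (22.8 to 25.3). Mfap5, a microfibril protein (ENSMUSG00000030116.14, chromosome 6, 122505845 to 122529290, protein coding), was at 538 CPM against 2.21 CPM, a ratio of 244 (193 to 312). Tnmd, a marker of tendon and ligament cells, was 59.9-fold higher (53.6 to 67.1) and Omd, for osteomodulin, 89.0-fold (77.0 to 103). Bmp3 was 57.7-fold higher (51.9 to 64.4). Moxd1, Nupr1, Srpx2, Lgals3, Cxcl1, S100a4, Igfbp7 and Dpt had ratios from 45.3 to 233. Of 13 basement membrane and adhesion genes, 8 were higher and 0 lower (median 1.27, percentile 99.9), with Hspg2, for perlecan, at 197 CPM against 23.9 CPM. Without members open to free RNA, 3 of 4 were higher.

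Genes lower in the P12 mesenchyme again included those of division and fetal growth. All 20 mitosis genes were lower (median -1.99, percentile 0), among them Mki67 at 9.70 CPM against 64.1 CPM. Of 18 DNA replication genes, 16 were lower and 0 higher (median -2.03, percentile 0), with Mcm5 at -2.81. Of 14 fetal growth and imprinted genes, 12 were lower and 0 higher (median -1.71, percentile 0). Igf2bp1 had 0 UMIs against 75.1 CPM, at least 90.3-fold lower, and Hmga2 (ENSMUSG00000056758.14, chromosome 10, 120361275 to 120476469, protein coding) was at 11.4 CPM against 234 CPM. Cdkn1c was at 308 CPM against 2298 CPM and Kcnq1ot1, the imprinted noncoding RNA of the same gene region, at 62.1 CPM against 664 CPM. Sox11 was at 14.4 CPM against 358 CPM and the surface protein gene Cd24a at 10.2 CPM against 226 CPM. Nfib was at 66.2 CPM against 724 CPM. H2afx, H2afy, Tead2, Stmn1 and Top2a had log2 ratios from -2.52 to -2.29.

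Among patterning genes in the mesenchyme, 6 of 23 odontogenic transcription factors were higher and 6 lower at P12 (median -0.37, percentile 13.5). Pitx1 was at 56.0 CPM against 395 CPM, Dlx5 at 14.1 CPM against 115 CPM and Dlx6 at 8.03 CPM against 63.8 CPM. Runx2, which drives osteoblast differentiation, was at 247 CPM against 71.1 CPM. Of 24 Wnt pathway genes, 12 were higher and 4 lower (median 0.92, percentile 99.98), with Wnt5a at 769 CPM against 63.7 CPM and Wnt10a at 71.2 CPM against 2.51 CPM. The inhibitor gene Dkk3 was 12.5-fold higher (11.3 to 13.8). Of 22 BMP and TGF-beta pathway genes, 6 were higher and 5 lower (median 0.03, percentile 80.2), and Tgfb1 was 15.4-fold higher (13.2 to 17.9). Of 15 FGF pathway genes, 6 were lower and 2 higher (median -0.77, percentile 0.39). The higher ones were the receptors Fgfr1, at 443 CPM against 171 CPM, and Fgfr2, and Dusp6, a feedback gene, was at -1.32. Of 11 hedgehog pathway genes, 4 were lower and 0 higher (median -0.91, percentile 2.58), with Cdon at -1.84. Of 6 ectodysplasin pathway genes, 2 were higher and 1 lower (median 0, percentile 52.5), Tnfrsf19 at 107 CPM against 24.8 CPM. The count of 2 was 1 at Leiden resolutions 0.5 and 2 and under 8 other alternatives.

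In the mesenchyme, 14 of 16 immediate early and stress genes were higher at P12 and 0 lower (median 3.06, percentile 100), with Zfp36 21.9-fold (20.3 to 23.6) and Ier3 22.6-fold (20.6 to 24.9) higher. Of 12 ion and pH transport genes, 3 were higher and 1 lower (median 0.07, percentile 90.4). Without members open to free RNA, 1 was higher. Of 13 enamel matrix and ameloblast genes, 10 were higher and 0 lower (median 4.75, percentile 100), but 10 of the 13 were open to free RNA, and the other 3 were all higher. Amelx was at 175 CPM in P12 mesenchyme, with a UMI in 35.4% of cells, against 29166 CPM and 64.0% in the epithelium. Of 8 hemoglobin and red cell genes, 3 were lower and 0 higher (median -0.59, percentile 11.0), and 7 of the 8 were open to free RNA. The count of lower ones was 8 with at least 200 genes per cell, at Leiden resolution 2 and with both libraries clustered together. Hbb-y, an embryonic globin, had 0 UMIs at P12 against 1286 CPM at E14.

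Mitotic transcripts were counted per cell after thinning each cell to 2000 UMIs. At E14, 52.4% of epithelial cells (45.7 to 59.0%) and 28.7% of mesenchymal cells (27.3 to 30.1%) held at least 3 UMIs of the mitosis list. At P12 the shares were 2.09% of epithelial cells (9 of 430, 0.961 to 3.94%) and 3.73% of mesenchymal cells (31 of 831, 2.55 to 5.25%). In E14 red cells, with a median of 15983.5 UMIs before thinning against 9621 in epithelial and 7392 in mesenchymal cells, the share was 8.63% (6.34 to 11.4%), and without thinning 57.8%. At P12, 15 of 17 red cells (88.2%, 63.6 to 98.5%) held such UMIs. Red cells were kept only with at least 500 genes, and the barcodes that this removed held mostly hemoglobin. The kept P12 red cells had a median of 912 genes, against 621 to 667 in the E14 red clusters. A difference in division between stages cannot be read from these shares. Thinning counted hemoglobin UMIs too, so the red cell shares are not comparable with those of other classes either. Among P12 epithelial clusters, cluster 8 had 7 such cells of 135. Cluster 9, whose cells carried markers of maturation-stage ameloblasts, which no longer divide, had 0 of 123 (upper limit 2.95%), and clusters 10 and 17 had 0 of 131 and 0 of 41. Thinning was drawn at random and separately for the class and each cluster, so the cluster counts do not add up to that of the class. Without thinning, clusters 8, 9, 10 and 17 had 24, 4, 20 and 2 such cells. Without thinning the epithelial and mesenchymal shares were 81.2% and 59.1% at E14 and 11.6% and 5.29% at P12. Free RNA enters these counts too, and no cell cycle phase was called.

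**Figure D3:**
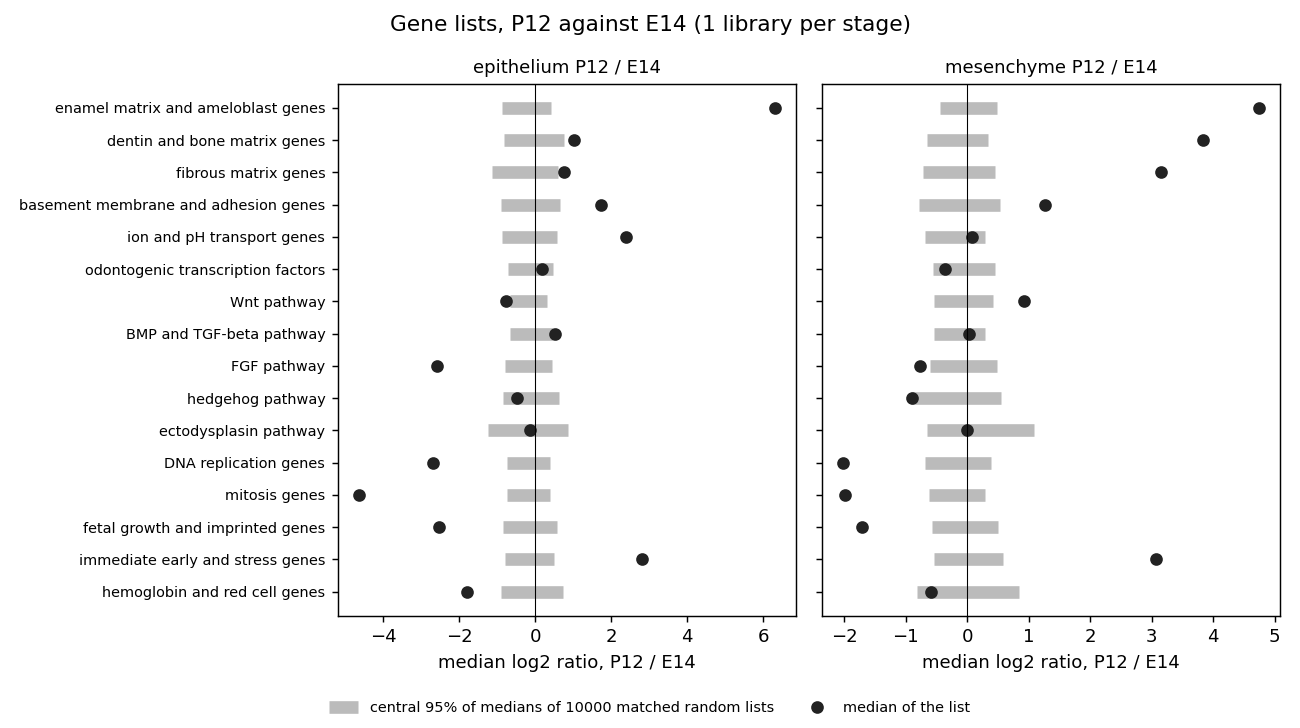
Median log2 ratio of P12 against E14 (horizontal axis, points) of each of the 16 gene lists in the epithelium and the mesenchyme, with grey bars for the central 95% of medians of 10000 matched random lists. Mitosis genes had medians of -4.64 in the epithelium and -1.99 in the mesenchyme, and enamel matrix genes 6.32 and 4.75, the latter mostly from members open to free RNA.

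At E14 the epithelium was compared with the mesenchyme to find genes that separate these interacting tissues, neither of them divided into dental and other cells. The epithelium was higher in several transcription factors. Sox2 (ENSMUSG00000074637.7, chromosome 3, 34650405 to 34652461, protein coding) was at 111 CPM against 0.537 CPM, a ratio of 207 (129 to 354), Tbx1 had a ratio of 104 (51.8 to 236) and Irx1 43.5 (30.7 to 62.6). Barx2 was at 228 CPM against 2.92 CPM. Barx1, its paralogue of molar mesenchyme (ENSMUSG00000021381.4, chromosome 13, 48662998 to 48666507, protein coding), went the other way, at 29.0 CPM against 352 CPM. Of the 23 odontogenic transcription factors, 9 were at least 2-fold higher in the epithelium and 11 lower (median -0.15, percentile 15.95, mean 0.18). Msx1 (ENSMUSG00000048450.10, chromosome 5, 37820485 to 37824583, protein coding) was at 36.4 CPM against 427 CPM.

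Signalling genes were also divided between the tissues at E14. Of 16 FGF pathway genes, 8 were higher in the epithelium and 3 lower (median 0.80, percentile 100). Fgf20, a ligand of the enamel knot (ENSMUSG00000031603.14, chromosome 8, 40279166 to 40308331, protein coding), was at 34.1 CPM against 0.119 CPM, a ratio of 286 (108 to 1071). Fgf9 was 11.0-fold higher (7.96 to 15.2), and the receptor gene Fgfr1 was lower, at 52.3 CPM against 171 CPM. Of 25 Wnt pathway genes, 10 were higher and 7 lower (median -0.35, percentile 5.20, mean 0.93). The ligand genes Wnt4 and Wnt6 were 36.8-fold (29.7 to 45.9) and 110-fold (76.9 to 162) higher, and Kremen2 64.1-fold (43.9 to 96.3). Of 22 BMP and TGF-beta pathway genes, 3 were higher and 9 lower (median -0.81, percentile 0.01). Bmp4 was at 1.94 CPM against 32.8 CPM, Inhba at 13.2 CPM against 89.8 CPM and Tgfb3 at 5.81 CPM against 44.3 CPM, while Bmp7 was at 44.1 CPM against 13.5 CPM. Of 12 hedgehog pathway genes, 2 were higher and 5 lower (median -0.71, percentile 1.09), with the mesenchymal coreceptor gene Gas1 at 118 CPM against 449 CPM. The count of 5 was 2 with doublets kept and 3 with a 3-fold limit. Of 6 ectodysplasin pathway genes, 3 were higher and 0 lower (median 1.06, percentile 99.1), with the adaptor gene Edaradd 5.80-fold higher (4.59 to 7.30).

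Of 13 basement membrane and adhesion genes, 9 were higher in the E14 epithelium and 2 lower (median 3.82, percentile 100). Lama5 was 46.1-fold (27.7 to 79.9), Col17a1 36.6-fold (23.3 to 59.0) and Itgb4 23.1-fold (15.8 to 34.0) higher. Pdgfa, Mt1, Spint2, Ifitm3, Meis2 and Cd24a were also higher, with ratios from 3.86 to 24.9. The mesenchyme was higher in matrix and imprinted genes. Of 12 fibrous matrix genes, 10 were lower in the epithelium and 0 higher (median -2.53, percentile 0), and of 13 dentin and bone matrix genes, 8 were lower and 0 higher (median -1.09, percentile 0). Col1a1, the type I collagen chain, was at 87.1 CPM against 957 CPM, and Ibsp, for bone sialoprotein, at 3.87 CPM against 140.4 CPM. Of 14 fetal growth and imprinted genes, 8 were lower and 0 higher (median -1.50, percentile 0), with Mest at 129 CPM against 1239.6 CPM and Dlk1 at 122 CPM against 793 CPM. Fibin, Ebf1, Osr2, Osr1, Igf1 and Lgals1 had log2 ratios from -4.43 to -3.47.

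Of 18 DNA replication genes, 2 were higher in the E14 epithelium, Uhrf1 at 2.67-fold and Fen1 at 2.07-fold, and 0 lower (median 0.36, percentile 99.8). None of the 20 mitosis genes reached a 2-fold ratio (median 0.36, percentile 99.9). Of 12 ion and pH transport genes, 3 were higher and 1 lower (median -0.28, percentile 19.5, mean 0.21), Car12 at 5.67-fold. Of 7 enamel matrix and ameloblast genes that could be measured, 2 were higher and 2 lower (median 0, percentile 53.3). Of 16 immediate early and stress genes, 2 were higher and 1 lower (median -0.30, percentile 4.27, mean 0.10), with Atf3 at 53.0 CPM against 1.67 CPM and Socs3 at 16.3 CPM against 49.6 CPM. Of 8 hemoglobin and red cell genes, all open to free RNA, 2 were higher and 0 lower (median 0.50, percentile 99.9). The mesenchymal class here pooled 13 clusters, among them 1 with the bone gene Ibsp and 1 with the tendon gene Scx among its leading genes, so its levels are averages over several cell types.

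At P12 the same comparison set 4 epithelial clusters against 5 mesenchymal clusters. Of 15 enamel matrix and ameloblast genes, 14 were higher in the epithelium and 0 lower (median 6.80, percentile 100). Enam, for enamelin, was at 1959.5 CPM against 6.10 CPM, a ratio of 322 (212 to 513), and Amelx had a ratio of 167 (154 to 181), Odam 165 (145 to 187), Amtn 150 (116 to 197) and Klk4 139 (90.9 to 225). Acpt, an acid phosphatase gene of enamel formation, had a ratio of 170 (57.8 to 827). Csn3 (ENSMUSG00000001622.15, chromosome 5, 87925579 to 87932665, protein coding) was at 271 CPM against 0.554 CPM (2 UMIs), a ratio of 488 (135 to 4039). The desmosome genes Pkp1 and Dsc3 had ratios of 153 (69.9 to 417) and 132 (71.6 to 276). Of 13 basement membrane and adhesion genes, 8 were higher and 5 lower (median 4.98, percentile 100), with Lama3 at 87.6 CPM against 0 UMIs, at least 105-fold higher. Of 12 ion and pH transport genes, 10 were higher and 0 lower (median 2.55, percentile 100). The chloride channel gene Cftr was at 38.3 CPM against 0 UMIs, at least 46.1-fold higher, and Car12 69.8-fold higher (29.6 to 216).

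Matrix genes again lay on the mesenchymal side at P12, by wider ratios. Of 12 fibrous matrix genes, 11 were lower in the epithelium and 1 higher (median -5.07, percentile 0), with Aspn at 2.95 CPM against 1467 CPM and Col3a1 at 63.1 CPM against 6732 CPM. Of 13 dentin and bone matrix genes, 12 were lower and 0 higher (median -4.82, percentile 0). Col1a1 was at 139 CPM against 17830.0 CPM, Dspp had 0 UMIs against 160 CPM (at least 181-fold lower) and Spp1, for osteopontin, was at 0.884 CPM against 557 CPM. Chodl, Omd, Mfap4, C1qtnf3, Bmp3, Foxf1 and Srpx2 had log2 ratios from -8.72 to -7.30. Msx1 and Barx1 were again lower in the epithelium, at 4.72 CPM against 364 CPM and 2.06 CPM against 193 CPM, and Lhx8 was at 0.884 CPM against 109 CPM. Tbx1 was 41.1-fold higher (13.7 to 202). Of 23 odontogenic transcription factors, 12 were higher and 8 lower (median 1.07, percentile 100).

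Among signalling lists at P12, 12 of 23 Wnt pathway genes were lower in the epithelium and 6 higher (median -1.02, percentile 0.02). The inhibitor genes Sfrp1 and Dkk2 were at 7.37 CPM against 444 CPM and 3.83 CPM against 301 CPM, and the receptor gene Fzd6 was at 49.5 CPM against 0.831 CPM. Of 12 FGF pathway genes, 7 were lower and 0 higher (median -1.30, percentile 0.06), with Spry1 at -3.89. Of 21 BMP and TGF-beta pathway genes, 6 were lower and 3 higher (median 0.13, percentile 93.4, mean -0.52), with Id1, a BMP target gene, 6.93-fold higher (5.66 to 8.56) and Tgfb3 at -4.60. Of 12 hedgehog pathway genes, 2 were higher and 3 lower (median -0.37, percentile 8.18), with Gas1 at -3.06. Of 6 ectodysplasin pathway genes, 3 were higher and 1 lower (median 0.81, percentile 98.3), with Tnfrsf19 at -1.51. Of 12 fetal growth and imprinted genes, 6 were lower and 1 higher (median -1.72, percentile 0.04), with Mest at 11.5 CPM against 366 CPM and Grb10 at 4.13 CPM against 168 CPM. Of 20 mitosis genes, 19 were lower and 0 higher (median -2.32, percentile 0), Cdk1 at -2.84, and of 18 DNA replication genes, 3 were lower and 0 higher (median -0.32, percentile 25.0). Of 16 immediate early and stress genes, 5 were lower and 2 higher (median -0.45, percentile 4.21), Atf3 6.08-fold higher (5.50 to 6.75). With a 3-fold limit 0 of them were lower and the balance turned. Of 5 measured hemoglobin and red cell genes, 1 was lower (median -0.75, percentile 6.13). That count was 0 with both other gene minimums, both other mitochondrial limits, both other resolutions and under further alternatives.

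Some of the P12 values between tissues depended on the naming and the clustering. Cluster 7, with Dspp at 999 CPM and Bglap at 13853 CPM, kept its mesenchymal name through Bglap2 and Mmp13 among its leading genes. With Leiden resolution 2, the log2 ratios of Dspp and Bglap were 7.58 and 4.93 rather than -7.50 and -5.56, when 9 mesenchymal cells joined a cluster named epithelial, and the dentin and bone matrix genes lower in the epithelium were 6 rather than 12. With doublets kept, the median of the odontogenic transcription factors was -0.15 rather than 1.07. TMM scaling moved the median of all genes by 0.12 and the total without abundant genes by 0.15 on the log2 scale.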

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

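The tests of free RNA for Bglap and of damaged cells for the immediate early genes were chosen only after the results were seen. Some genes differed in opposite directions in the 2 tissues between P12 and E14, and these differences were not tested. Dlx5, a homeobox gene of tooth and bone patterning, had a log2 ratio of 2.06 in the epithelium and -3.02 in the mesenchyme. Sfrp1, a secreted Wnt inhibitor, had -3.41 and 1.24, and Nkd1, a Wnt feedback inhibitor, -2.31 and 1.05. The feature tdTomato, one of the transgene entries that no comparison used, had 19 UMIs in the E14 library, all in epithelial cells, and 143 in the P12 library, 139 of them in epithelial cells. Whether these UMIs are sequence shared with the DsRed reporter entry was not tested.

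Bglap and Bglap2, known as bone genes, had UMIs in P12 epithelial cluster 9, whose cells carry markers of maturation-stage ameloblasts (Bglap at 211 CPM, 179 to 249). Free RNA from osteoblast-like cells would reach all epithelial clusters alike, but after thinning 26.0% of cells in cluster 9 (18.5 to 34.7%) and 0.326% in the other epithelial clusters (upper limit 1.80%) had a Bglap UMI. Droplets that also held an osteoblast-like cell would carry its collagen, but cells of cluster 9 with a Bglap UMI had Col1a1 at 29.0 CPM (11.7 to 59.8), against 617 CPM needed, or 433 CPM if judged by the 5 cells that hold 90% of the Bglap UMIs of osteoblast-like cluster 7. Both technical explanations are thus at odds with these values, and expression by the ameloblast-like cells may be the source, as a hypothesis from 1 library. Whether it depends on stage stays open, since the E14 library had no such cluster.

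Enamel matrix UMIs appeared in P12 cells outside the epithelium. After thinning, 21.2% of mesenchymal, 19.3% of endothelial, 17.3% of perivascular and 27.5% of macrophage cells had an Amelx UMI, against 49.1% of epithelial cells. Pooled over these classes outside the epithelium the share was 20.7% (18.5 to 23.1%, 253 of 1221 cells). Unnamed cells, red cells and neutrophils were not in that pool. The pooled share lay inside the interval of each class, which free RNA from ameloblast-like cells would also give. Mesenchymal cells were 831 of the pooled cells, and the perivascular (9.57 to 27.8%) and macrophage intervals (14.6 to 43.9%) were wide. The test could thus hardly have gone against free RNA, which stays possible. Levels were less alike, with Amelx at 432 CPM in red cells, 393 CPM in perivascular cells, 90.6 CPM in endothelial cells and 0 CPM in the 8 neutrophils. Droplets with an ameloblast-like cell as well stay open as a further source, because 35.0% of the Amelx UMIs outside the epithelium lay in 6 cells with 10 or more, between the shares set for and against. Stage as a biological explanation was not tested.

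Immediate early and stress genes were higher at P12 in the epithelium (15 of 16 at least 2-fold), mesenchyme (14) and endothelium (15). With cells of at most 5% mitochondrial UMIs the epithelial median log2 ratio was 2.80, against 2.81, so removing cells with a high mitochondrial share did not lower it. That limit took out 88 P12 epithelial cells, and 19 more lost their name. List medians of the P12 epithelial clusters ran from 0.61 to 3.12, so a changed mix of clusters could hide an effect of damage. The mesenchyme and endothelium were not tested in this way. A difference in dissociation or handling between the libraries may contribute, since 16 of 16 members were at least 2-fold higher at P12 in macrophages too (median 3.25). That P12 class was 1 cluster of 40 cells, with chemokine genes such as Ccl7, Ccl2 and Ccl3 among its leading genes. Unnamed cluster 13, of 102 cells with Lyz2 and Tyrobp among its leading genes, was not in it. The count of 16 may thus not hold for all P12 macrophages. A difference in handling is also confounded with stage. The 2 cannot be told apart, because each stage is 1 library. In P12 epithelial cluster 9 only 5 of 16 members were higher and 4 were lower than in the E14 epithelium.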

How the results depend on the processing

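Every alternative was a value with no test, since each stage is 1 library, so no replicate was left out. No paired analysis was possible because there was 1 library per stage and no unit pairs them. Placing unnamed clusters in their best class, counting lists without members open to free RNA, and all alternatives of the endothelium were chosen after the data were seen. Of the class shares, list counts and mitotic shares, 1220 values under alternatives stayed the same, 134 moved and 6 turned, and of the other results, mostly gene ratios and list medians, 5083 stayed the same, 487 moved and 8 turned. For the first kind the values that moved or turned follow by alternative, and for the other results those that turned, with the main value in brackets. Where no cause is named the cause was not tested. Dspp gave no value in the mesenchyme between stages at resolution 2, nor in it or between the P12 tissues with at most 5% mitochondrial UMIs. At E14, 7 of 15 enamel genes had 3 or more UMIs in either tissue and the others could not be compared. Some classes had 0 cells at a stage in the main run and appeared under an alternative only. These were P12 lymphocytes, 1.84% with at most 20% mitochondrial UMIs and also at resolution 2, E14 neuronal cells, 1.71% at resolution 2, and 1 unnamed P12 cluster, 5.07% of cells, that took the osteoclast name with unnamed clusters in the best class. That name rests on the score alone, since its 10 leading genes held 0 osteoclast markers and 2 of another class. Clustered together, 0.386% of E14 cells were neutrophils and 0.353% perivascular, and 0.298% of P12 cells were skeletal muscle and 0.199% glial.

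With at least 200 genes per cell, 569 further red cells entered at E14 and 560 mesenchymal cells lost their name, and the E14 shares were 54.1% mesenchymal (67.3%), 16.5% red (8.57%) and 13.3% unnamed (6.40%), with 3.396% red at P12 (0.845%). In the mesenchyme between stages 8 hemoglobin genes were lower (3) and 1 ectodysplasin gene higher (2), and at P12 0 hemoglobin genes were lower in the epithelium (1), with Hbb-bt at 0.58 (-1.13). With at least 1000 genes, red cells were 1.13% at E14 (8.57%) and 2.03% at P12 (0.845%), unnamed cells 12.6% (6.40%) and 11.5% (16.7%), P12 macrophages 5.58% (1.99%) and P12 neutrophils 0% (0.398%), 1 mesenchymal ectodysplasin gene was higher (2) and 0 P12 hemoglobin genes lower (1). With at most 5% mitochondrial UMIs, the P12 epithelial share was 17.2% (21.4%), the mesenchymal shares 66.0% at E14 (67.3%) and 43.8% at P12 (41.3%), the unnamed shares 7.89% (6.40%) and 12.5% (16.7%), P12 macrophages 6.07% (1.99%), P12 neutrophils 1.76% (0.398%), 3 hedgehog genes were lower in the epithelium between stages (1), and 0 P12 hemoglobin genes were lower (1). With at most 20%, the E14 mesenchymal share was 57.5%, unnamed cells 16.3% and 11.1%, P12 macrophages 5.63%, 2 epithelial hedgehog genes were lower (1), 1 mesenchymal ectodysplasin gene higher (2) and 0 P12 hemoglobin genes lower (1).

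With doublets kept, 21 P12 epithelial cells joined the mesenchyme, E14 chondrocytes were 3.65% (4.18%), P12 macrophages 5.63%, P12 neutrophils 1.96% and P12 unnamed cells 11.9%. In the epithelium between stages 2 fibrous matrix genes (4) and 7 odontogenic transcription factors (9, the balance turned) were higher and 4 hedgehog genes lower (1). Also, 1 mesenchymal ectodysplasin gene was higher (2), 2 hedgehog genes lower (5) and 1 replication gene higher (2) in the E14 epithelium, and the P12 median of the transcription factors was -0.15 (1.07). At resolution 0.5 the mesenchymal shares were 63.1% at E14 and 48.2% at P12, E14 chondrocytes 0%, P12 macrophages 7.06% and unnamed cells 14.9% and 4.48%, 1 mesenchymal ectodysplasin gene (2) and 1 E14 replication gene (2) were higher and 0 P12 hemoglobin genes lower (1). At resolution 2, 9 mesenchymal cells joined a cluster of 38 cells named epithelial, with Dspp at 1714 CPM and Bglap at 23039 CPM. The P12 ratios then were 7.58 for Dspp (-7.50), 4.93 for Bglap (-5.56) and 0.45 for Hbb-bt (-1.13), dentin and bone matrix genes higher in the epithelium between stages were 11 (5), and those lower in the P12 epithelium 6 (12). The E14 mesenchymal share was 64.4%, E14 macrophages 1.38% (2.52%), unnamed cells 8.80% and 15.02%, 8 mesenchymal hemoglobin genes were lower (3), 1 ectodysplasin gene higher (2) and 0 P12 hemoglobin genes lower (1).

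With listed genes in the clustering, the P12 mesenchymal share was 45.0% (41.3%), E14 chondrocytes and P12 neutrophils 0%, P12 macrophages 5.52%, unnamed cells 10.2% at both stages, and 1 mesenchymal ectodysplasin gene was higher (2). Clustered together, 249 chondrocytes joined the mesenchyme, whose shares were 68.9% and 47.7%. E14 chondrocytes were then 0%, P12 endothelial cells 18.5% (13.7%), macrophages 5.97% and neutrophils 1.54%, and unnamed cells 8.50% and 0%. There 1 ectodysplasin gene was higher (2) and 8 hemoglobin genes lower (3), 1 E14 replication gene was higher (2), 0 P12 hemoglobin genes were lower (1), Hbb-bt was at 1.12 (-1.13) and endothelial Meg3 at 0.14 (-5.11). With unnamed clusters in the best class, mesenchymal shares were 73.7% and 48.2%, P12 endothelial cells 18.4%, unnamed cells 0% by construction, Meg3 was at 0.062, 1 mesenchymal ectodysplasin gene was higher (2) and 0 P12 hemoglobin genes lower (1).

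With the mean of per-cell CPM, 3 hedgehog (1) and 2 ectodysplasin genes (1) were lower in the epithelium between stages, 1 mitosis gene (0) and 1 hemoglobin gene (2) higher in the E14 epithelium, and 5 hedgehog (3) and 0 hemoglobin genes (1) lower in the P12 epithelium. The total without abundant genes gave 0 P12 hemoglobin genes lower (1). With a floor of 10 UMIs, 0 epithelial hedgehog genes were lower (1), 5 basement membrane genes (8) and 3 transcription factors (6) higher in the mesenchyme, and 1 enamel gene (2) and 1 immediate early gene (2) higher in the E14 epithelium. Without members open to free RNA, the epithelium between stages had 2 dentin and bone (5) and 1 fibrous matrix gene (4) higher and 0 hemoglobin genes lower (7), the mesenchyme 3 enamel (10), 3 basement membrane (8) and 1 ion transport gene (3) higher and 0 hemoglobin genes lower (3), and the E14 epithelium 0 hemoglobin genes higher (2). The labels of list counts follow the side with more members. On the other side, the epithelium between stages had 5 transcription factors (8) and 1 basement membrane gene (3) lower without these members, the E14 epithelium 0 ion transport genes lower (1) and the P12 epithelium 3 basement membrane genes lower (5). Smaller sides were not followed under the other alternatives.

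A 1.5-fold limit by construction counts more members. It gave 5 epithelial (1) and 7 mesenchymal (4) hedgehog genes lower between stages, 5 ectodysplasin (3), 5 replication (2), 2 mitosis (0) and 3 immediate early genes (2, the balance turned) higher in the E14 epithelium, and 6 replication (3) and 4 hemoglobin genes (1) lower in the P12 epithelium. A 3-fold limit counts fewer, 4 hemoglobin genes lower in the epithelium (7), 5 basement membrane (8), 1 ion transport (3) and 1 ectodysplasin gene (2) higher and 2 FGF (6) and 2 hedgehog genes (4) lower in the mesenchyme. In the E14 epithelium it gave 3 hedgehog genes lower (5) and 0 replication genes higher (2), and in the P12 epithelium 1 replication (3), 0 immediate early (5, the balance turned) and 0 hemoglobin genes lower (1).

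Thinned to 1000 UMIs, the mitotic shares at E14 were 34.9% of epithelial and 20.5% of mesenchymal cells (52.4% and 28.7%), by construction lower. With at least 1 UMI they were 76.0% and 62.3%, with P12 shares of 20.9% and 15.6% (2.09% and 3.73%), and with at least 5 UMIs the E14 shares were 41.5% and 21.9%.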

Other observations

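The P12 epithelial clusters differed from each other in list medians and in single genes when each was set against the E14 epithelium, a comparison made after the data were seen. In cluster 9, with markers of maturation-stage ameloblasts, 14 of 15 enamel matrix and ameloblast genes and 11 of 12 ion and pH transport genes were at least 2-fold higher (medians 7.64 and 3.38). Odam was at 51079 CPM there and at 204 CPM in cluster 17, while Enam, for enamelin, was at 21247 CPM in cluster 17 and 126 CPM in cluster 9. In cluster 17, with the secretory matrix genes Amelx and Enam among its leading genes, 11 of 12 enamel genes and 8 of 11 ion transport genes were higher (medians 7.98 and 2.11). Cluster 10, led by Slc26a7, Tfrc and Slc4a4, had 11 of 12 enamel genes and 7 of 11 ion transport genes higher (medians 2.72 and 2.31). Cluster 8, led by Lgals7, Krt15 and Krt17, carried 7 of 9 markers of keratinizing oral epithelium. Of its enamel genes 8 of 9 were higher (median 2.43), and 11 of its 22 odontogenic transcription factors were lower and 2 higher. Some of these enamel counts were at background level. Amelx was at 66.2 CPM in cluster 8 and 98.8 CPM in cluster 10, against 175 CPM in P12 mesenchyme. The higher enamel genes that were also above every other P12 class of 20 or more cells were 14 in cluster 9, 11 in cluster 17, 9 in cluster 10 and 3 in cluster 8. All 20 mitosis genes were lower than at E14 in each of the 4 clusters, with medians from -4.84 to -2.93. Sums under 3 UMIs were set to the floor, which is a higher CPM in clusters with fewer UMIs. These medians can thus be bounds, and they do not rank the clusters by how much lower the genes were.

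Endothelial cells, compared between stages after the data were seen (275 cells at P12, 83 at E14), shared the lower fetal and mitosis genes. Of 14 fetal growth and imprinted genes, 13 were at least 2-fold lower at P12 (median -3.29), with H19 at 249 CPM against 1812 CPM, Igf2 at 45.0 CPM against 481 CPM and Mest at 276 CPM against 2473 CPM. Without Dlk1, Peg3 and Meg3, which were open to free RNA, 10 of 11 were lower. Unnamed P12 cluster 14, of 95 cells and endothelial by score, was not in the class. With that cluster placed in it, Meg3 was no longer lower. Plagl1, Maged2, Asb4, Cdkn1c and Tmem255a had log2 ratios from -3.58 to -2.55. Of 20 mitosis genes, 19 were lower (median -2.01), and 15 of 16 immediate early and stress genes were higher (median 2.68). Higher at P12 were the water channel gene Aqp1, at 1976 CPM against 22.2 CPM, Igfbp7, at 7412 CPM against 70.3 CPM, and Itih5, at 501 CPM against 2.29 CPM (3 UMIs), a ratio of 219 (74.5 to 1062). S100a6 was 107-fold higher (67.7 to 181) and Ly6c1 46.5-fold (30.8 to 73.6), and Lrg1, Ly6a and Eln were at 331, 246 and 234 CPM against 2.29, 2.29 and 1.53 CPM.

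The red reporter transcript, counted as DsRed, was highest in the epithelium. It was at 8244 CPM in E14 epithelial cells (94.8% of cells) and 39.7 CPM in mesenchymal cells (16.2%), and at 33949 CPM in P12 epithelial cells (97.7%) and 592 CPM in mesenchymal cells (62.3%). P12 endothelial cells had 1165 CPM (64.7%), and in the P12 classes outside the epithelium 58.8 to 75% of cells had a UMI. The ends of that range were 17 red cells and 8 neutrophils, and the shares were not thinned to equal depth. Levels were less alike, from 202 CPM in red cells to 1165 CPM in endothelial cells. Free RNA stays possible, and the source of these UMIs was not tested. Median depths were 9621 and 7392 UMIs at E14 and 5315.5 and 3866 UMIs at P12.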
